A study of Homo sapiens with 6 samples.

How the data were processed

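The samples were 6 RNA samples of T24 bladder carcinoma cells, 3 transduced with lentivirus expressing a hairpin RNA against TRIP13 and 3 with a control vector. Per the labels' protocols, total RNA was isolated with RNAiso Plus and turned into biotinylated cRNA with the GeneChip 3' IVT Express kit. Per the file headers, the values come from PrimeView CEL files. The background correction, the summarization of probes and the genome build of the alignments are not given in the sources used here. The labels name the samples of each group as biological replicates, without saying whether they were separate transductions, so the p-values measure the spread between these samples.

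The deposited raw sheet holds a linear intensity for each of 49395 probe sets, from 4.61 to 25144. From the values, these intensities had already been made alike between arrays, since the sorted log2 values of any pair of arrays differed by at most 0.147. The deposited normalized sheet holds log2 values relative to the median of the 6 arrays for each probe set: taking log2 of the raw sheet and subtracting that median gave the same values to within 2.1e-06. The deposited series matrix holds the same log2 values. The sheet also holds the authors' p-value for each probe set, raw and corrected, which were recomputed here as those of an equal-variance comparison of the groups with Benjamini-Hochberg correction over the sheet. The authors' deposited count of changed genes, their number of entries in each direction, matched the length of their lists. No label gives a scan date or batch. Each group carries its own sample code in the array names, so handling of the groups cannot be told apart from the knockdown. Detection calls were not used here. A normalization that makes arrays alike removes any change shared by most genes, so each value measures a gene relative to the others on its array.

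The 102 Affymetrix control probe sets were set aside, which left 49293 for testing. Of these, 187 had a number in the symbol cell and 381 had no symbol, and both kinds were tested as unnamed. Another 2470 named several genes and were tested without being given to a gene. Among 46255 probe sets with 1 gene symbol, 46053 had a gene identifier that was found in a RefSeq gene table, and 3947 symbols were updated through it. A gene was read from its single-symbol probe set of highest mean signal, which gave 18597 genes. Coordinates were printed only as the authors' file gives them.

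The comparison of 3 knockdown with 3 control arrays was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the deposited log2 values, with group as the only factor and two-sided tests. Benjamini-Hochberg adjustment ran over all 49293 probe sets, with an adjusted p of 0.05 as the threshold. The prior had 2.88 degrees of freedom. SDs are between the 3 arrays of a group, and SEs are those of limma. An exact permutation test of 3 against 3 cannot go below 0.1. Gene lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and with an estimated correlation, and with fry, each adjusted over 20 lists. The lists were spindle checkpoint, G2 and mitosis, DNA replication, non-homologous end joining, homologous recombination, ErbB receptors with ligands and adaptors, ERK pathway output, epithelial, mesenchymal, interferon response, NF-kB and cytokines, unfolded protein and amino acid stress, cholesterol synthesis, hypoxia and glycolysis, luminal urothelial, basal urothelial, meiotic chromosome axis, ribosomal proteins, and markers of immune, endothelial and fibroblast cells. Of the 425 genes of the 20 lists, 406 were measured. Some results, among them 1 list, are not reported here.

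The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took TRIP13, MAD2L1, MAD2L1BP, CDC20, BUB1B and EGFR, then the 6 highest and 6 lowest fold changes among called genes whose groups did not overlap. From each list it took the largest rise and the largest fall among called members, or the 2 largest changes where members passed in 1 direction only, and for a list without calls the member of smallest p. This gave 52 genes. Genes outside the rule are named as picked after their values were seen.

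The scripts were tested on simulated arrays with the same number of probe sets and arrays, in which 50 genes each had been changed by 1.2, 1.5, 2 and 3-fold. In this simulation the fit recovered 20% of the 1.2-fold, 72% of the 1.5-fold, 96% of the 2-fold and 100% of the 3-fold changes. Of the called probe sets, 4% were unchanged ones. Few genes were changed, while 32.7% of real probe sets passed, so these shares need not hold for the real arrays. With no list changed, camera called 0 lists, and with every member of 1 list lowered alike it called 1. Noise was drawn independently for each probe set, so these calls do not show how camera behaves with correlated genes.

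Alternatives were the series matrix, quantile normalization, median centring and cyclic loess of the raw signals, the brightest 70% or 50% of probe sets, eBayes with trend and robust, array weights, the replicate number as a block, leaving out each array, the mean of all probe sets of a gene, an estimated correlation, stricter thresholds and an unmoderated test. Scaling to the poly-A spike-ins, the tests on control probe sets and chromosome arms, the tests on gene ontology terms and the spindle checkpoint list without TRIP13 were added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the figures.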

Results

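RNA was measured in T24 cells, an established human line derived from a urinary bladder carcinoma. The cells had been transduced with a lentivirus. In 3 samples the virus carried a short hairpin RNA against TRIP13, and in 3 samples it carried a control vector. TRIP13 is an AAA+ ATPase that remodels MAD2 and other HORMA domain proteins, and it acts in the spindle assembly checkpoint, in meiosis and in DNA repair. Total RNA from each sample was labelled with biotin and hybridized to 1 Affymetrix PrimeView array, a 3' expression array. The labels call the samples of each group biological replicates 1 to 3. No untransduced cells and no further hairpin were analysed here. The median log2 signal of an array lay between 6.14 and 6.16, and the median of the array's background control probe sets lay between 2.96 and 3.05. Those 23 background probe sets varied widely: their mean was 4.40 in the knockdown and 4.36 in the control, and the brightest averaged 10.8. Across probe sets, arrays of 1 group correlated with r of 0.998 to 0.999, and arrays of different groups with r of 0.993. The 3' minus 5' log2 signal separated the groups: for ACTB it was 0.56 to 0.58 in the knockdown and 0.64 to 0.67 in the control, and for GAPDH 0.070 to 0.11 and 0.11 to 0.14, without overlap of the arrays. Precision is limited by the number of arrays, which is 3 in each group. All fold changes below are knockdown minus control on the log2 scale and are relative to the bulk of genes, because the deposited signals had been made alike between arrays. Control probe sets for the poly-A spike-ins, bacterial RNAs added to the sample before labelling, were higher on the knockdown arrays by 0.24. Scaling the arrays to those spike-ins, an alternative chosen after seeing the data, lowered each fold change by the same 0.24, and the median change of all genes from -0.012 to -0.25.

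TRIP13 itself was lower on all 3 knockdown arrays, whichever of its 2 probe sets was read. At the brighter probe set, 11731526_s_at, the linear signal was 387 ± 1.54 (SD, n = 3) in the knockdown and 852 ± 9.10 (SD, n = 3) in the control. That is 45.5% of the control level, a log2 fold change of -1.14 ± 0.035 (SE) with a limma adjusted p of 9.45e-06. The dimmer probe set, 11731525_at, read 183 ± 8.64 against 450 ± 12.4 (SD, n = 3), or 40.6% of the control level and a log2 fold change of -1.30 ± 0.049 (SE). The file places both probe sets on chromosome 5 from 892757 to 918160 on the plus strand, in coordinates whose genome build is not given in the sources used here. Every array therefore lay on the side of TRIP13 expression that its label names. The authors' deposited table gives the same differences, -1.30 and -1.14.

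**Figure D1:**
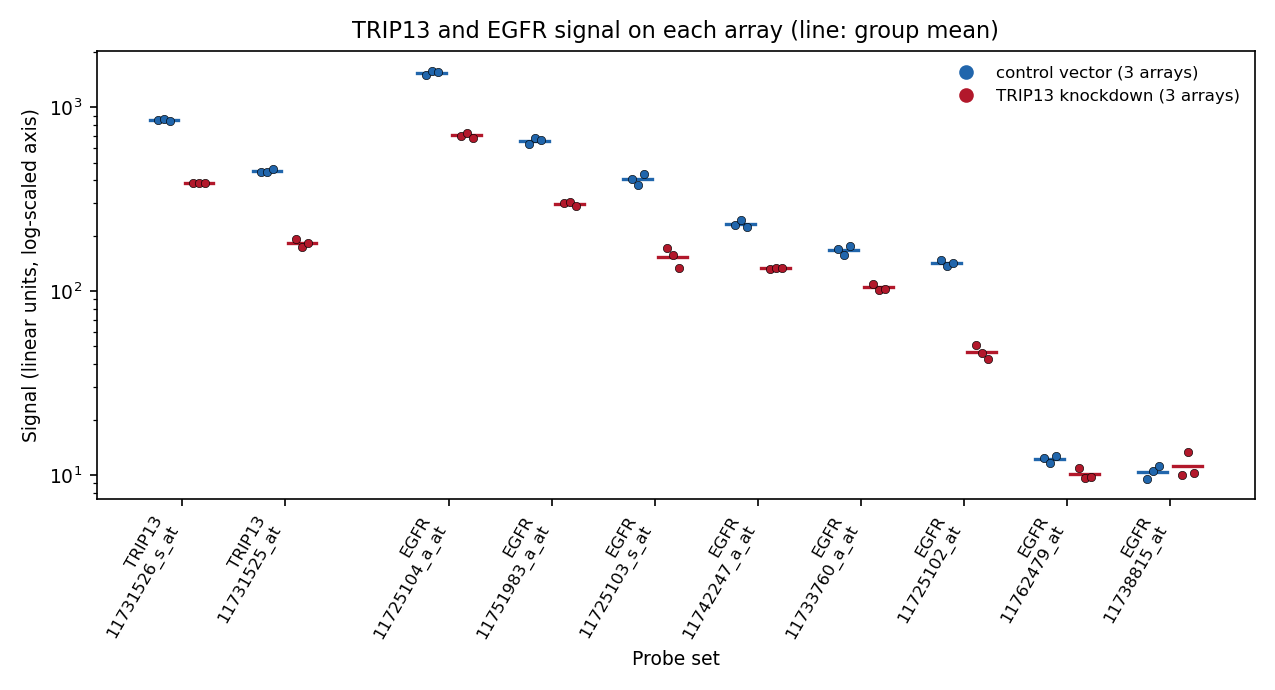
Linear signal on a log-scaled axis for the probe sets of TRIP13 and EGFR, with a point for each of the 3 knockdown (red) and 3 control (blue) arrays and a line at each group's mean. Both TRIP13 probe sets were lower on every knockdown array. Of the 8 EGFR probe sets, 7 were lower past the threshold, while the dimmest, with signals near 10, was not. Another dim EGFR probe set, at 10.1 against 12.2, is among the 7.

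Knockdown of TRIP13 was accompanied by many changes, most of them small. Of 18597 genes, 6399 (34.4%) passed an adjusted p of 0.05 in limma, with 3255 higher and 3144 lower in the knockdown. The median size of change among them was 0.30 on the log2 scale, against a median SD within groups of 0.058. A change of at least 1.5-fold was met by 842 of these genes, 403 higher and 439 lower, and a change of at least 2-fold by 160, 78 higher and 82 lower. Counted over probe sets, 16101 of 49293 passed, 8631 higher and 7470 lower. The 3 knockdown values all lay on one side of the 3 control values for 8999 genes (48.4%), where chance gives 10%. With arrays scaled to the poly-A spike-ins, 13730 genes passed, 1134 higher and 12596 lower, so the balance of rises and falls holds only relative to the bulk of genes. An adjusted p of 0.01 left 4248 genes.

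The largest fall was that of SERPINB2, a serine protease inhibitor of the urokinase pathway, which dropped to 0.109 of its control level (log2 fold change -3.19 ± 0.065 SE, adjusted p = 6.93e-06, n = 3). FGFBP1, a secreted carrier of fibroblast growth factors, fell by 2.10 on the log2 scale, and EDNRA, an endothelin receptor, fell by 1.82. ID1, an inhibitor of basic helix-loop-helix transcription factors and a target of BMP signalling, fell by 1.74 at a bright probe set and fell past the threshold at all 3 of its probe sets. PRR16 fell by 1.70 and FBXO27, an F-box protein, fell by 1.69. The largest rise was that of ANGPTL4, a secreted inhibitor of lipoprotein lipase, which was 4.43-fold higher (log2 fold change 2.15 ± 0.064 SE, adjusted p = 8.42e-06, n = 3). EGR1, an immediate early transcription factor, was 4.18-fold higher, with 5 of its 6 probe sets past the threshold. BTF3L4 was higher by 1.98 on the log2 scale, MYBL1, a MYB family transcription factor, by 1.97, and MZT1, a component of the gamma-tubulin ring complex, by 1.80. PLCXD2 was higher by 1.71 at its brighter probe set, while its other probe set changed by -0.0078, and the mean over both gave 0.85. All of these calls held without any 1 of the arrays.

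**Figure D2:**
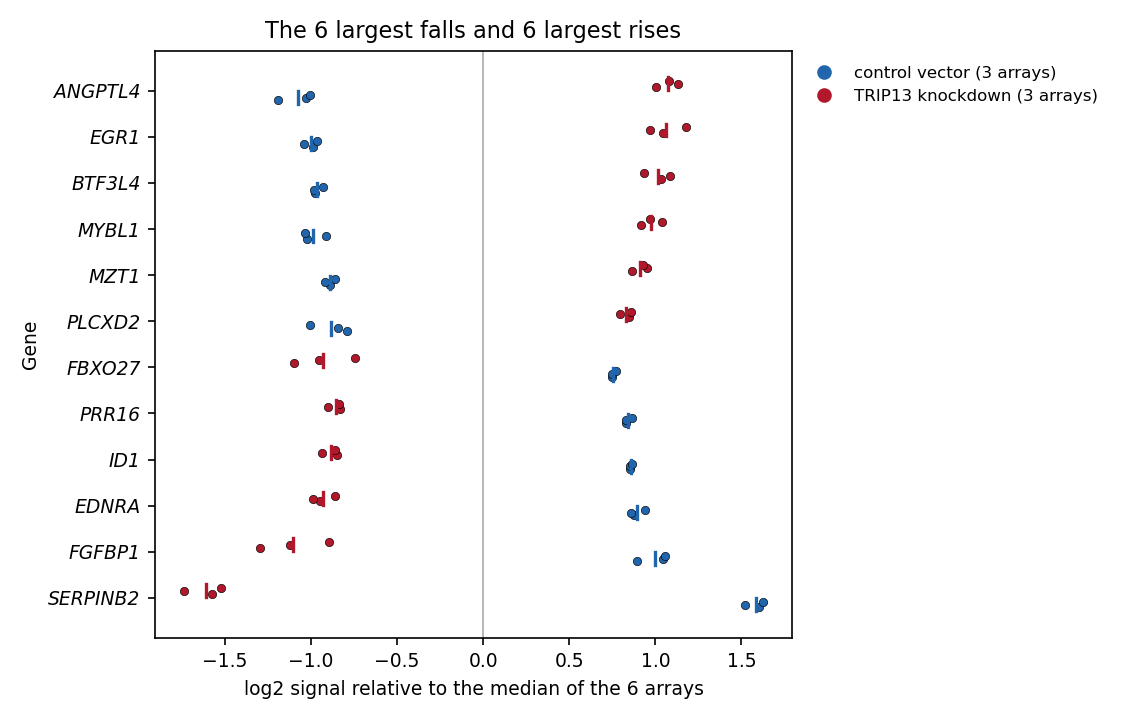
Log2 signal relative to the median of the 6 arrays for the 6 genes with the largest falls and the 6 with the largest rises, with a point for each of the 3 knockdown (red) and 3 control (blue) arrays and a line at each group's mean. In each of these genes the groups did not overlap, from SERPINB2, which changed by -3.19, to ANGPTL4, which changed by 2.15.

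Genes of the spindle assembly checkpoint went both ways. Of 21 measured members, 4 rose, 5 fell and 12 did not pass (5 and 5 adjusted over the list alone), and the list did not shift relative to other genes (camera adjusted p = 0.955). By fry, which makes no comparison with other genes, it passed as lower (adjusted p = 0.0019). TRIP13, the target, is 1 of the 5 falls. With it left out, which was chosen after seeing the data, 4 of 20 rose and 4 fell (5 and 4 adjusted over the list alone), with a mean of 0.00075 (camera adjusted p = 0.818), and fry did not call the list (adjusted p = 0.412). MAD2L1, which encodes the HORMA protein MAD2 that TRIP13 remodels, fell by 0.37 ± 0.066 (SE) on the log2 scale (adjusted p = 0.0051), at 3 of its 4 probe sets, and the mean over all of them gave -0.23. MAD2L1BP, the adaptor p31comet that brings TRIP13 to MAD2, had a log2 fold change of 0.11 ± 0.043 (SE) and an adjusted p of 0.0884. It passed among the brightest 70% (adjusted p = 0.0462) and 50% (adjusted p = 0.0239) of probe sets and with trend and robust variances (adjusted p = 0.0187), and with scaling to the poly-A spike-ins it turned to -0.13 (adjusted p = 0.0280). BUB1B had a log2 fold change of -0.069 ± 0.039 (SE) and an adjusted p of 0.230, and passed with that scaling (-0.31, adjusted p = 8.17e-04). NDC80, of the outer kinetochore, rose by 0.28, a call that ended with scaling to the poly-A spike-ins (0.039, adjusted p = 0.562). CDC20, the activator of the anaphase-promoting complex, had a log2 fold change of 0.14 ± 0.039 (SE) with an adjusted p of 0.0319. That call rested on the probe set and the arrays: its 3 probe sets ranged from -0.11 to 0.14 with a mean of 0.046 (adjusted p = 0.418), the call ended without any 1 of the arrays except control replicate 2 (0.13 to 0.15, highest adjusted p = 0.0966) and with median centring (adjusted p = 0.0502), and with scaling to the poly-A spike-ins the value was -0.099.

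The wider G2 and mitosis list shifted upward relative to other genes. Of 29 measured members, 13 rose and 3 fell, and the same counts passed adjusted over the list alone (camera adjusted p = 0.0125). The call ended with an estimated correlation within the list (adjusted p = 0.239) and among the brightest 50% of probe sets (adjusted p = 0.0846). It also ended with scaling to the poly-A spike-ins (adjusted p = 0.185), where the list's mean turned from 0.11 to -0.13. That scaling lowered every gene alike, so the list's fold change relative to other genes was unchanged by it. MKI67, singled out after its values were seen, is among the rises by its brightest probe set (0.17), while 4 of its 6 probe sets passed as lower, down to -0.39. HMMR, a spindle-associated hyaluronan receptor, rose by 0.52 ± 0.042 (SE), and CDC25B, a phosphatase that activates CDK1, fell by 0.44 ± 0.038 (SE). Among the other members, picked after their values were seen, CDC25C was higher by 0.44, BIRC5 by 0.40 and PRC1 by 0.39. Of 35 genes of DNA replication, 6 rose and 10 fell (7 and 11 adjusted over the list alone), with no shift of the list relative to other genes (camera adjusted p = 0.955), and 1 of the called members had a probe set past the threshold in the opposite direction. CCNE2, a cyclin of the G1/S transition, rose by 0.78 and MCM4, a subunit of the replicative helicase, fell by 0.60. MCM6 and CDC6, also picked after their values were seen, were higher by 0.55 and 0.61.

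Genes of DNA double-strand break repair also went both ways. In homologous recombination, 4 of 23 measured members rose and 7 fell (5 and 7 adjusted over the list alone), with a camera adjusted p of 0.616. BRCA1 fell by 0.42 ± 0.040 (SE) at 4 of its 5 probe sets, with a mean of -0.27 over all of them, and RAD51AP1 rose by 0.28 ± 0.044 (SE), a call that ended with scaling to the poly-A spike-ins (0.042). In non-homologous end joining, 2 of 15 measured members rose and 2 fell (4 and 4 adjusted over the list alone), with a camera adjusted p of 0.866. LIG4, the DNA ligase of this pathway, rose by 0.46 and RIF1, which counters end resection, fell by 0.42.

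EGFR, the receptor of epidermal growth factor, was lower in the knockdown. Its brightest probe set, 11725104_a_at, read 702 ± 24.1 in the knockdown and 1544 ± 38.5 in the control (SD, n = 3), a log2 fold change of -1.14 ± 0.044 (SE) with an adjusted p of 1.60e-05. The 8 probe sets of EGFR ranged from -1.61 to 0.094, and 7 passed, all lower. The exception, 11738815_at, read 11.2 ± 1.83 against 10.4 ± 0.810. Among the 7 that passed, 11762479_at was about as dim, at 10.1 against 12.2 (adjusted p = 0.0154). The file places the brightest probe set on chromosome 7 from 55086713 to 55275325, again with no build given. The lists for ErbB signalling and for the output of the ERK pathway were picked knowing that a published study of these samples discusses EGFR signalling, so their choice was not blind to it. Of 25 measured ErbB receptors, ligands and adaptors, 4 rose and 6 fell, the same counts as adjusted over the list alone, with a camera adjusted p of 0.866, and 2 of these called members had probe sets past the threshold in the opposite direction. HBEGF, a ligand of EGFR, rose by 0.80 ± 0.037 (SE). EREG, another ligand, picked after its value was seen, was lower by 1.04 (log2 fold change -1.04). Of 20 genes induced by ERK activity, 8 rose and 7 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.616), and 1 called member had a probe set past the threshold in the opposite direction. EGR1 rose by 2.06 and DUSP4, a phosphatase of the ERK kinases, fell by 0.96. Their directions differed across the list: SPRY4, EPHA2 and SPRY1, picked after their values were seen, were higher by 0.80, 0.76 and 0.62, while PHLDA1, FOSL1 and MYC had log2 fold changes of -0.63, -0.57 and -0.54. SPRY4 passed at 1 of its 3 probe sets, the lowest of which was at 0.015.

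Among markers of cell state, the epithelial list had 2 of 16 measured members higher and 4 lower, the same counts as adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.0911). Some members were dim: CDH1, picked after its values were seen, had a mean log2 signal of 4.01 in the knockdown and 4.13 in the control. DSP, the desmosomal protein desmoplakin, fell by 0.72 ± 0.041 (SE). GRHL2, a transcription factor of epithelia, had a log2 fold change of 0.26 ± 0.072 (SE) with an adjusted p of 0.0311, at 1 of its 5 probe sets, and the mean over all of them was 0.025 (adjusted p = 0.733). The call for GRHL2 ended without knockdown replicate 2 (0.20, adjusted p = 0.0757), without control replicate 1 (0.26, adjusted p = 0.0783) and without control replicate 2 (0.21, adjusted p = 0.0888), and with scaling to the poly-A spike-ins (0.020). Of 18 measured mesenchymal markers 4 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.866). ACTA2, smooth muscle actin, rose by 1.71 ± 0.069 (SE) at 1 of its 3 probe sets, with 0.0029 as the lowest value of the 3 and a mean of 0.58, and SNAI2, a repressor of epithelial genes, fell by 0.67 ± 0.042 (SE). CCN2 and CCN1, secreted matricellular proteins picked after their values were seen, were higher by 1.41 and 0.73. Of 12 luminal urothelial markers none rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.178). ELF3 and FOXA1, transcription factors of luminal urothelium, fell by 0.78 and 0.74, and the mean over the probe sets of FOXA1 was -0.48. Of 10 basal urothelial markers 1 fell, also adjusted over the list alone (camera adjusted p = 0.866), and this was the desmosomal cadherin DSC3, which fell by 0.35 at 2 of its 3 probe sets.

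Interferon-response genes were lower in the knockdown. Of 29 measured members, 17 fell and 4 rose (18 and 4 adjusted over the list alone), and the list had the smallest camera p of the 20 lists (adjusted p = 4.64e-05). With an estimated correlation it missed the threshold (adjusted p = 0.142). OASL, a relative of the oligoadenylate synthetases, fell by 1.40 ± 0.038 (SE; adjusted p = 7.65e-06). Among the other members, picked after their values were seen, IFIT2, IFI44, DDX60 and IFIT3 had log2 fold changes of -1.14, -0.85, -0.84 and -0.83. IRF9, the DNA-binding subunit of the interferon-stimulated transcription factor, went the other way and rose by 0.49 ± 0.036 (SE) at all 4 of its probe sets. The mean of the list was -0.38. The ontology term for type I interferon signalling, tested after seeing the data, had 15 of 44 genes lower and 5 higher with a median of -0.070, and did not pass (camera adjusted p = 0.457 over 714 terms). In the list of NF-kB targets and cytokines 10 of 19 members rose and 5 fell (11 and 5 adjusted over the list alone). The list did not pass (camera adjusted p = 0.0981). With scaling to the poly-A spike-ins it passed (adjusted p = 0.0259), while its mean turned from 0.10 to -0.14. Since that scaling lowered every gene alike, the list's fold change relative to other genes did not move. IL11 rose by 1.29 ± 0.066 (SE) at its brightest probe set, with 0.50 as the lowest value of its 3 probe sets and a mean of 0.78, and PTGS2, the inducible cyclooxygenase, fell by 0.86 ± 0.040 (SE).

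Genes of hypoxia and glycolysis shifted upward relative to other genes, with 10 of 20 measured members higher and 2 lower (11 and 3 adjusted over the list alone; camera adjusted p = 0.0051). The call ended with an estimated correlation (adjusted p = 0.142) and among the brightest 50% of probe sets (adjusted p = 0.0535). The estimate for this list was -0.030, below the preset 0.01, so a higher correlation among members was not why that call ended. With scaling to the poly-A spike-ins the mean of the list turned from 0.22 to -0.019. ADM, the vasodilator peptide adrenomedullin, rose by 1.01 ± 0.038 (SE), and VEGFA fell by 0.22 ± 0.038 (SE). ANKRD37, ENO2 and SLC2A1, picked after their values were seen, were higher by 0.79, 0.71 and 0.66, ANKRD37 at 1 of its 2 probe sets, the other being at -0.057. In the list for unfolded protein and amino acid stress, 3 of 21 measured members rose and 10 fell (4 and 13 adjusted over the list alone; camera adjusted p = 0.0997). The largest changes were opposite: DNAJB9, a chaperone of the endoplasmic reticulum, was 2.82-fold higher at the brightest of its 3 probe sets, 2 of which passed, and PHGDH, the first enzyme of serine synthesis, fell by 0.95 ± 0.035 (SE). For cholesterol synthesis 5 of 19 measured members rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.866). MVD rose by 0.32, a call that ended with scaling to the poly-A spike-ins (0.081), and DHCR7 fell by 0.34.

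The lists for the meiotic chromosome axis, for ribosomal proteins and for other cell types showed few calls. Of 15 measured genes of the meiotic chromosome axis, where TRIP13 acts in germ cells, only SYCP2 passed, with a log2 fold change of -0.28 ± 0.074 (SE), and none did adjusted over the list alone (camera adjusted p = 0.937). The SYCP2 signal, at a mean log2 of 3.20 in the knockdown and 3.47 in the control, was close to that of the background probe sets, and the call ended without any 1 of the arrays except knockdown replicate 3 (-0.30 to -0.22, highest adjusted p = 0.0776). Of 19 measured ribosomal protein genes none rose and 3 fell, or 1 adjusted over the list alone (camera adjusted p = 0.379). RPL7 fell by 0.19 ± 0.035 (SE). RPL10A had a log2 fold change of -0.13 ± 0.036 (SE), and its call ended without any 1 of the 6 arrays (-0.14 to -0.12, highest adjusted p = 0.0936) and with quantile normalization (-0.078, adjusted p = 0.140). With scaling to the poly-A spike-ins the ribosomal list passed as lower (mean -0.27, adjusted p = 0.0338), though its fold change relative to other genes was unchanged. Of 17 measured markers of immune, endothelial and fibroblast cells, only PDGFRA passed, with 0.13 ± 0.040 (SE), and none did adjusted over the list alone (camera adjusted p = 0.866). The PDGFRA call ended without any 1 of the 6 arrays (0.10 to 0.15, highest adjusted p = 0.132), with median centring (adjusted p = 0.0625), with trend and robust variances (adjusted p = 0.229) and with the mean over its 4 probe sets (0.061, adjusted p = 0.173), and with scaling to the poly-A spike-ins the value was -0.11.

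**Figure D3:**
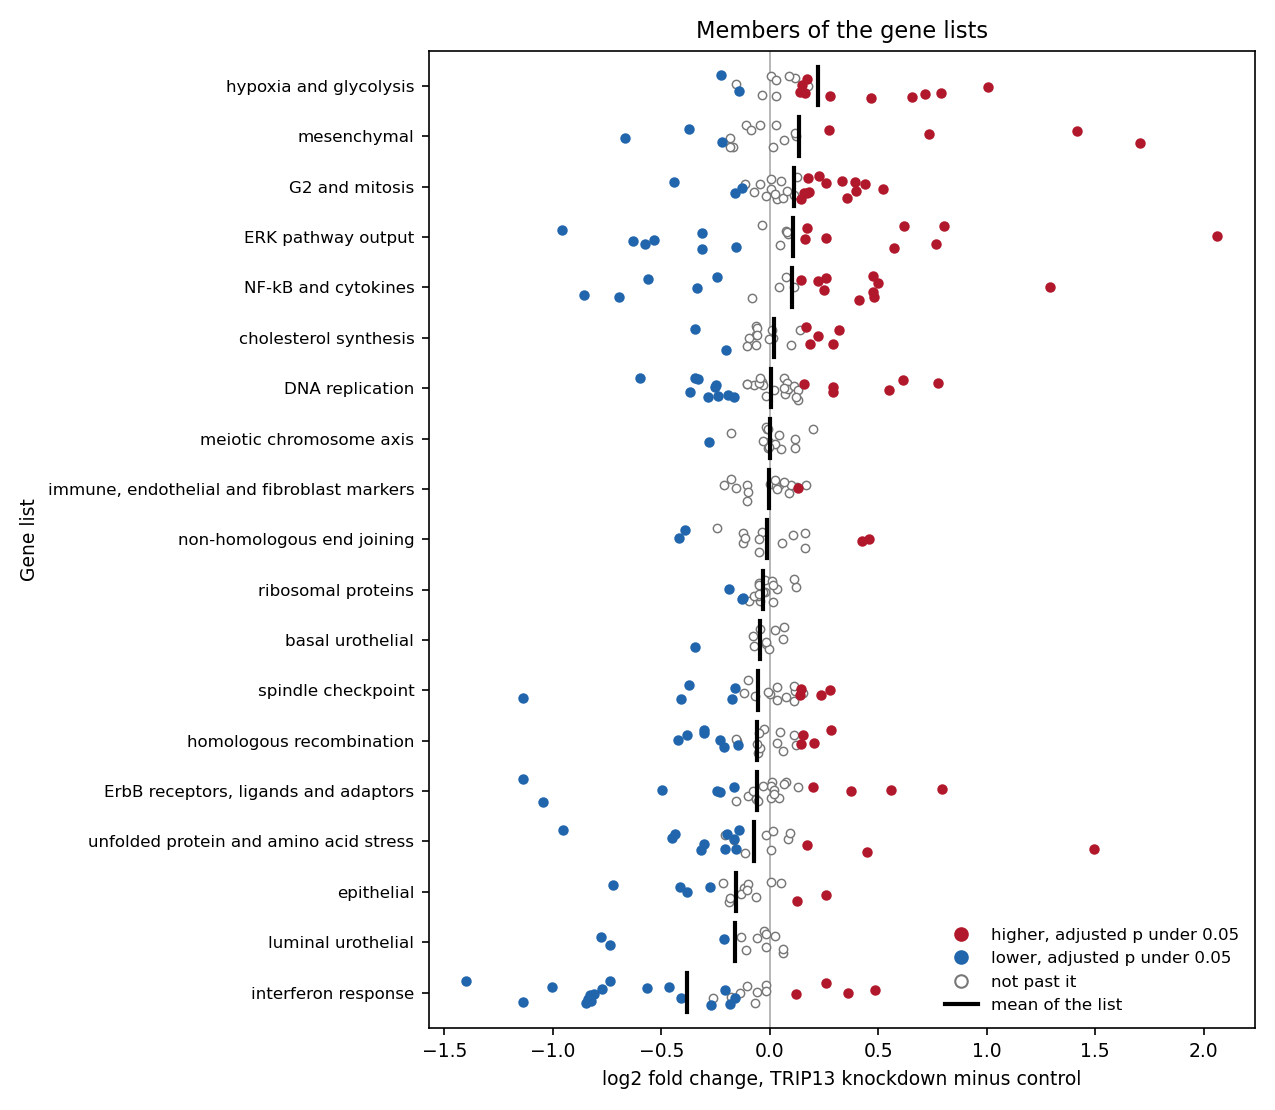
Log2 fold change, knockdown minus control, of each measured member (points) of the gene lists, with filled points past an adjusted p of 0.05 and a bar at each list's mean. The interferon list has the lowest mean (-0.38), and the hypoxia and glycolysis (0.22) and G2 and mitosis (0.11) lists passed as higher relative to other genes. No list passed with an estimated correlation (adjusted p = 0.142 for the interferon and hypoxia lists and 0.239 for G2 and mitosis), and the means of the latter 2 were below 0 once arrays were scaled to the poly-A spike-ins.

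Across the 20 lists, 4 passed camera with its preset correlation of 0.01 and 7 had an unadjusted p under 0.05. With the correlation estimated for each list, none passed and 3 had an unadjusted p under 0.05. Against the preset 0.01, the estimates were 0.020 for interferon response, 0.038 for G2 and mitosis and -0.030 for hypoxia and glycolysis. A higher correlation therefore does not account for the loss of the hypoxia call, whose unadjusted camera p rose from 7.6e-04 to 0.021. The setting thus raised p without a higher correlation, so the interferon and G2 losses cannot be put down to correlation alone. By fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, 14 lists passed, and by its mixed form, which asks for change in either direction, 18 did. In 7 lists the median, the mean and the direction of the test differed in sign. These were the spindle checkpoint, DNA replication, ErbB, mesenchymal, cholesterol, meiotic and other-cell-type lists, none of which passed camera.

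The authors' deposited table of changed genes has 588 entries listed as higher and 587 as lower in the knockdown, which come from 1105 probe sets. Each entry has a fold change of at least 1.5 and a corrected p under 0.05. In the authors' full deposited table, 1999 probe sets meet both limits, of which 894 are not in that list. The list has 1175 rows with 1175 distinct symbols, so further probe sets of a listed symbol would not appear in it. How many of the 894 are of that kind was not counted here. By the moderated test used here, 2036 probe sets met the same limits, 1033 higher and 1003 lower. Of the 6399 called genes, 205 had a probe set past the threshold in the direction opposite to that called. Among 12040 genes with more than 1 probe set, REEP5 and BRWD1, picked because of this disagreement, were the 2 genes with probe sets past 1.5-fold in both directions.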

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

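All tests in this part on control probe sets, on chromosome arms and on the interferon list were chosen after the result was seen, while the splits of the arrays were planned.

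Among control probe sets that no comparison uses, several kinds were higher on every knockdown array than on every control array. The poly-A spike-ins, bacterial RNAs added before labelling, were higher on the knockdown arrays by 0.16 (dap), 0.26 (lys), 0.20 (phe) and 0.33 (thr) on the log2 scale, at 24 of their 24 probe sets. Probe sets for ribosomal RNA were higher too, by 0.17 for 18S and 0.35 for 28S. The hybridization control bioB was higher by 0.13 and the background probe sets by 0.038. For the other hybridization controls the arrays of the groups overlapped, with differences of 0.089 (bioC), 0.038 (bioD) and 0.0096 (cre). The mean over all hybridization controls was higher by 0.074, with an SD of 0.077 among the knockdown arrays. Taken relative to that mean, the poly-A spike-ins were higher by 0.16, less than the 0.24 used for scaling. The 3' minus 5' log2 signal of ACTB and of GAPDH was lower on every knockdown array than on every control array, for ACTB 0.56 to 0.58 against 0.64 to 0.67.

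For the poly-A spike-ins, no explanation tested here is excluded. Genes within 0.5 log2 units of the spike-in probe sets had a median change of 0.016, but making the arrays alike holds that median near 0, so a shift of the whole array cannot be told apart from a change of the spike-ins alone. A common factor, such as less polyadenylated RNA per amount of total RNA in the knockdown or more spike-in mix, could raise all spike-ins alike. Their rises differed (permutation p = 0.0041, with probe sets of the same spike-in not independent). The hybridization controls also shifted unequally, from 0.0096 to 0.13, so equal rises need not be seen and the factor stays open. Separate handling of the groups cannot be told apart from the knockdown, because the mean spike-in signal differed by 0.24 between groups and by at most 0.027 within one, and each group carries its own sample code.

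The count of called genes was set against other splits of the 6 arrays, of which 10 exist, too few for a share under 0.05. The real split gave 6399 genes, 16101 probe sets and 4 lists, each reached by 1 split, the real one, while the highest of the other splits gave 0 genes, 0 probe sets and 1 list. Every other split mixes knockdown and control arrays, so a large difference between the groups widens the spread within its parts. Low counts there follow from any such difference and say nothing of its cause. Gain or loss of whole chromosome arms in the knockdown cells is argued against by the arm medians: among 41 arms the largest in size was 0.045 (8p, over genes of above-median signal), below the 0.3 set as the bound, and camera called 0 arms, with 2 at an unadjusted p under 0.05. Handling of the groups, effects of the hairpin on RNAs other than TRIP13, which were not tested, and effects of lower TRIP13 stay open for the breadth of the changes.

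The interferon-response list was lower with a mean of -0.38 (camera adjusted p = 4.64e-05, or 0.142 with an estimated correlation). IFNB1 changed by -0.030 (adjusted p = 0.820) at a mean log2 signal of 3.29, close to background. A stronger response to the virus in the control cells cannot be told apart from a weaker one in the knockdown, because no untransduced cells were analysed here and the list's mean of -0.38 fits either. A biological effect of lower TRIP13 on these genes is a hypothesis that these arrays leave open.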

How the results depend on the processing

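TRIP13 stayed lower and past the threshold under the 16 alternatives run for it, which leave out the mean of probe sets and the unmoderated test, from -1.14 to -1.13 with an array left out and at -1.38 with scaling to the poly-A spike-ins, which was chosen after seeing the data. Leaving out an array gave 5196 to 5644 genes, 12949 to 14223 probe sets and 4 lists. The count of genes moved to 842 with a 1.5-fold limit, 4248 at an adjusted p of 0.01 and 13730 with spike-in scaling (1134 higher, 12596 lower, 4352 of them called in both), and that of probe sets to 2036, 10261 and 34652. That scaling lowered every change by 0.24. Lists past the threshold fell from 4 to 1, the interferon list, among the brightest 50% of probe sets, where 17 lists were tested, and to 0 with an estimated correlation. They rose to 5 with spike-in scaling, 3 of them shared. There the NF-kB list (adjusted p = 0.0259) and the ribosomal list (adjusted p = 0.0338) passed, and the G2 and mitosis list did not (adjusted p = 0.185). Because every change was lowered alike, these moved calls are not shifts of fold change relative to other genes. With scaling to the poly-A spike-ins CDC20 and PDGFRA turned to -0.099 and -0.11 and lost the call (adjusted p = 0.0596 and 0.0528), while MAD2L1BP, not called before, turned from 0.11 to -0.13 and passed (adjusted p = 0.0280). For other settings the causes were not tested. Same-numbered arrays showed little shared deviation (correlations 0.0037, 0.050 and 0.019). Arrays of differing number ranged from -0.071 to 0.054, the highest being knockdown replicate 3 with control replicate 1. With all of these near 0, the values do not decide whether the numbers pair the samples. The replicate block gave 5551 genes, 14152 probe sets, 4 lists and -1.14 for TRIP13, and CDC20, GRHL2, SYCP2, RPL10A and PDGFRA missed the threshold with it. Under the 861 combinations of named genes and alternatives, 813 kept their side of the threshold, 43 lost the call, 2 of them turning in sign, and 5 gained one. The series matrix holds the same values as the normalized sheet, so agreement under it was fixed in advance. The other normalizations started from signals already made alike between arrays, so they test that step only in part. Leaving TRIP13 out of the spindle checkpoint list, also chosen after seeing the data, left that list uncalled by camera and ended its call by fry (adjusted p = 0.412). GRHL2 and SYCP2 are dim and were removed by both filters, and FGFBP1 and PDGFRA by the stricter one. Signal over background limits what can be said of such dim genes.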

Other observations

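The tests on gene ontology terms in this part were chosen after seeing the data, and the genes were picked after their values were seen. Of the terms of the deposited annotation, some leaned lower and some higher. Of 35 genes of the term for cellular amino acid biosynthesis, 16 fell and 2 rose (limma camera adjusted p = 0.125 over 714 terms), so the term did not pass. Of the terms tested, 0 passed with camera and 60 had an unadjusted p under 0.05. Among terms that leaned higher, protein polyubiquitination had 19 of 52 genes higher and 5 lower (adjusted p = 0.270), response to unfolded protein 20 of 47 higher and 5 lower (adjusted p = 0.270), and mitotic sister chromatid segregation 8 of 16 higher and 0 lower (adjusted p = 0.299). The unfolded protein term thus leaned the other way from the fixed list for unfolded protein and amino acid stress, where 3 of 21 rose and 10 fell. PHGDH, PYCR1 and BCAT1, enzymes of serine, proline and branched-chain amino acid metabolism, had log2 fold changes of -0.95, -0.74 and -0.54. PSAT1, the enzyme after PHGDH in serine synthesis, had one of -0.44 with 8 of its probe sets lower past the threshold. The amino acid transporters SLC7A5 and SLC7A1 were at -1.12 and -1.06. In purine synthesis, where 8 of 17 genes of a term fell and 1 rose (adjusted p = 0.399), IMPDH2, PFAS, GART and PAICS were at -0.53, -0.50, -0.49 and -0.43.

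Other genes with changes of at least 2-fold were picked one by one after their values were seen, with no test of a group. BMPR2, a receptor of bone morphogenetic proteins, was at -1.06, and ID3, an inhibitor of basic helix-loop-helix factors, at -1.09. The thrombin receptor F2R and the related F2RL1 were higher by 1.69 and 1.58. CD69, a lymphocyte activation antigen, was higher by 1.64 at 1 of its 3 probe sets. CDK4, the cyclin D kinase, was at -1.33, and HMGA2, a chromatin protein, at -1.05. BID, a BH3-only protein of apoptosis, was at -1.36.

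REEP5 had 6 of its 10 probe sets higher and 4 lower past the threshold, from -0.65 to 0.61. BRWD1 had 4 of its 6 probe sets higher and 1 lower, from -0.65 to 1.04.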
